A study of Mus musculus with 9 samples.

How the data were processed

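RNA was measured by single-end sequencing (75 cycles, NextSeq500) of total RNA from the coronal suture of C57BL/6 mice at 7 months of age. There were 9 libraries, 3 in each of 3 groups: wild type (WT), Twist1+/- without surgery (MUT) and Twist1+/- with suture regeneration surgery at 1 month (REG). Per the labels every RNA sample had an integrity number above 9. Reads were aligned to mm10 with STAR 2.6.1d and processed in Partek per the submitters' processing notes. The counting method, annotation release, normalization and settings of the authors' test are not given in the sources used here.

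The deposited matrix holds 43644 unnamed values for each of the 9 libraries. From the values themselves, the deposited matrix is in upper-quartile scaled gene counts: the 75th percentile was about 2.76 in every library, and the most frequent values were multiples of a library-specific lowest value. Each value therefore reads as an estimated read number plus 1, times a factor per library. Many values are fractional multiples, so they were treated as a normalized unit and not as whole reads. The deposited gene table gives the authors' p-value and FDR, their log2 ratio, and the least-squares group mean as a signal, for each pair of groups. It also gives each gene's sum, maximum, geometric mean and arithmetic mean. Matrix columns were assigned to genes in the order of that table after all 4 statistics matched for 43644 of 43644 genes within a relative tolerance of 1e-06, and the set of 4 was unique for 43480 of them. Symbols were looked up in GENCODE M21 (GRCm38) for exon length and position, where 42973 (98.5%) were found, 42843 of these with an equal start.

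Estimated reads per library were obtained as the value over the library's lowest value, minus 1. They came to 16356391, 20019712 and 19886755 in WT, 10894209, 2945636 and 7860273 in MUT, and 39377876, 30272185 and 18276494 in REG. Depth in MUT was therefore the lowest, which limits the precision of low values there.

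The 3 comparisons (MUT vs WT, REG vs MUT and REG vs WT) came from 1 fit of all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend or robust options). The response was log2(value + 0.367), where 0.367 is 1 millionth of the median column sum. Genes at 0.367 or more in at least 3 libraries were tested (29107 genes). All p-values are two-sided and were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Values in the text are means of the deposited values with their SD (n = 3 unless stated), and log2 changes are given with the standard error of the fit. The smallest p of an exact permutation test of 3 against 3 is 0.1, so no such test was used. The protocol speaks of 3 pairs of samples, and the series design of 1 week after induction; the labels explain neither, so no pairing was used and the age of 7 months was taken from the sample labels. The labels do not say whether each library came from a different animal, and the p-values measure the spread between these libraries.

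A set of 34 gene lists was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each comparison. An estimated correlation per list and fry (directional and mixed) were alternatives. The groups, comparisons, tests, gene lists and naming rule were chosen before the data were examined. Named genes are Twist1; the 7 largest increases and 7 largest decreases per comparison among called genes whose groups did not overlap, leaving out predicted genes, RIKEN clones, pseudogenes, receptor segments, microRNAs and small nucleolar RNAs; and the members of smallest p in the lists. The rule also takes the 10 genes with the largest opposite changes in MUT vs WT and REG vs MUT. Where no gene was called, the 5 of smallest p per direction are given as values. The opposite movement of genes in MUT vs WT and REG vs MUT was counted, and set beside 100 simulations without effects and a cross-fit in which the comparisons shared no MUT library.

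Alternatives were trimmed-mean and quantile scaling, no and a 10 times stricter filter, pseudocounts 10 times lower and higher, limma with trend, array quality weights, only the 2 groups compared, a replicate block, each library left out in turn, and REG replicate 3 or REG replicates 1 and 2 alone. Total-read scaling, background subtraction and MUT replicate 2 alone were added after seeing the data. Background was the median number of reads per kb of exon over 1747 olfactory and vomeronasal receptor genes in each library. For the subtraction this density times each gene's exon length was taken off its estimated reads before scaling to reads per 1e+06 (RPM). The pipeline was tested on simulated data with 200 changed genes, raised and lowered in equal number. It recovered 0% at 2-fold in each comparison, at most 2.5% at 4-fold, and from 53% to 59% at 8-fold. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.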

Results

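Gene expression was measured in the coronal suture, the fibrous joint between the frontal and parietal bones of the skull, in 9 libraries from mice aged 7 months. Twist1 encodes a transcription factor, and its loss from 1 copy is a known cause of coronal synostosis, the early fusion of this suture. The groups were WT, MUT (Twist1+/-, no surgery) and REG (Twist1+/-, suture regeneration surgery at 1 month), with 3 libraries each. Estimated reads on genes ran from 16356391 to 20019712 in WT, from 2945636 to 10894209 in MUT and from 18276494 to 39377876 in REG.

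The libraries differed in signs of RNA and library quality along with their group. Olfactory and vomeronasal receptor genes, which are known from sensory neurons and serve here as a measure of background, took 2442 ± 877 reads per 1e+06 (RPM) in WT, 12930 ± 3880 in MUT and 2651 ± 1963 in REG (mean ± SD, n = 3). The background estimated from them was 7.86% of the reads in MUT replicate 2 and up to 23.2% in the other MUT libraries, against 0.509% to 0.867% in the other libraries. Mitochondrially encoded genes took 11.4% ± 1.91 of the reads in WT, 3.02% ± 1.52 in MUT and 12.5% ± 2.91 in REG. The repeat-like predicted gene Gm10800 took 101039, 23738 and 65299 RPM in MUT and from 4.24 to 35.4 in the other 6 libraries.

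The first principal component (64.8% of the variance of the 1000 most variable genes) parted MUT from the other groups, and the second (19.3%) parted REG replicates 1 and 2 from the rest. Spearman correlations across genes with the WT libraries were 0.91 to 0.95 for REG replicate 3, 0.80 to 0.82 for REG replicate 1 and 0.70 to 0.73 for REG replicate 2. The library names carry sheet numbers 2 and 3 for REG replicates 1 and 2, which repeat those of WT replicates 2 and 3, and 8 for REG replicate 3. The library of MUT replicate 2 is named MB4_S5, which does not give its group, and that of REG replicate 3 is named REG2_S8; groups and replicates follow the sample titles. A number is used once per sample sheet, so REG replicates 1 and 2 are taken to come from another run than WT replicates 2 and 3, and the labels do not say which other libraries shared it.

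**Figure D1:**
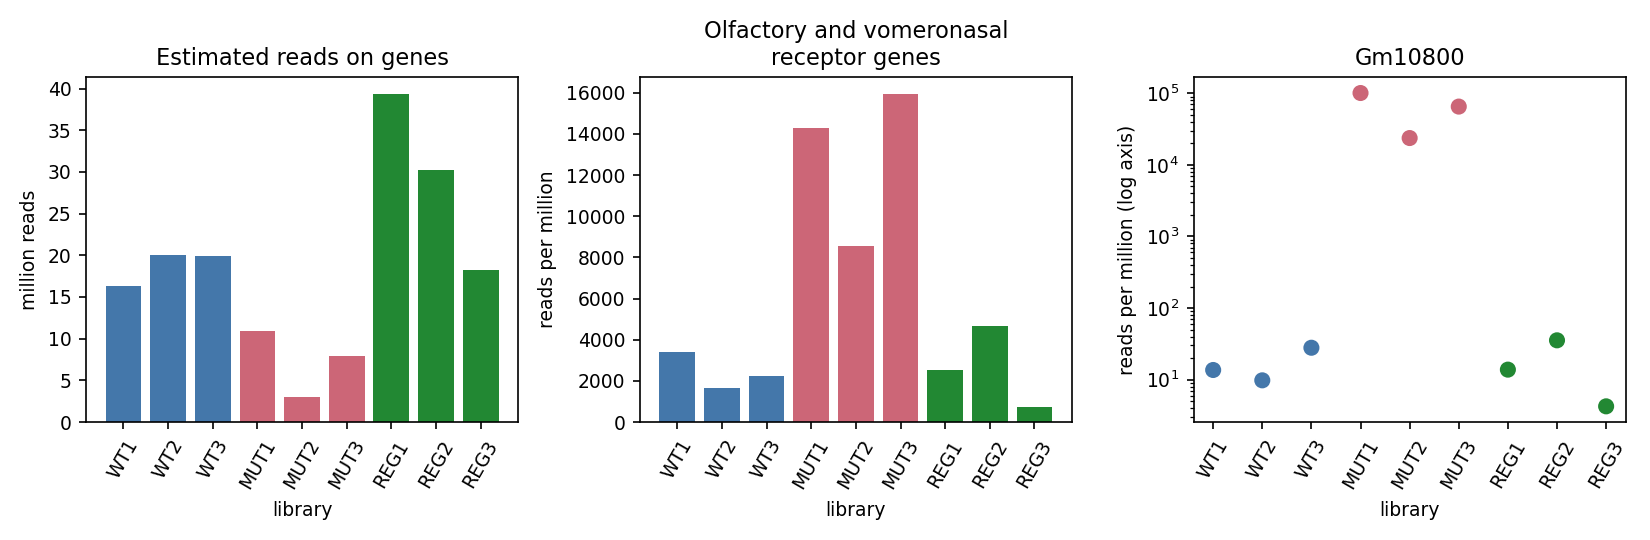
Estimated reads on genes (in units of 1e+06), RPM on olfactory and vomeronasal receptor genes, and RPM on Gm10800 (log axis) in each of the 9 libraries; bars and points are single libraries. The 3 MUT libraries have the fewest reads (2945636 to 10894209) and the most receptor reads (8555 to 15954 RPM).

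Twist1 (chromosome 12, 33957671 to 33959829, GRCm38) was measured first. Its deposited values were 16.2, 23.3 and 23.1 in WT (20.9 ± 4.02), 0.987, 8.08 and 0.548 in MUT (3.21 ± 4.23) and 3.76, 9.19 and 12.2 in REG (8.38 ± 4.27; mean ± SD, n = 3). It fell from WT to MUT (log2 change −3.26 ± 0.76, adjusted p = 0.0109, limma), with all 3 MUT libraries below all 3 WT libraries. REG lay between the other groups, and neither REG vs MUT (1.85 ± 0.76, adjusted p = 0.0808) nor REG vs WT (−1.40 ± 0.76, adjusted p = 0.567) passed the test. MUT replicate 2 decides much of this: the log2 change from WT was −1.31 with MUT replicate 2 alone (adjusted p = 0.223), and REG vs MUT was called without it (2.83, adjusted p = 0.00552). The MUT vs WT call also ended after background subtraction (−2.90, adjusted p = 0.0505). With total-read scaling it was kept, at a smaller change (−2.24, adjusted p = 0.0241). The MUT libraries also had a raised background. Under the 10 times stricter filter the median change of all genes in MUT vs WT was −0.99. The size of the Twist1 fall therefore cannot be read as the effect of genotype alone. In the authors' table Twist1 had a log2 ratio of −2.70 for MUT over WT with an FDR of 0.013.

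MUT vs WT asks how the unoperated Twist1+/- suture differs from the wild-type suture. The 7 named genes with the largest falls were led by Col3a1 and Tnn. Col3a1, a fibrillar collagen (chromosome 1, 45311538 to 45349706), fell from 6468 ± 2140 in WT to 28.4 ± 24.8 in MUT (n = 3, log2 change −8.13 ± 0.58, adjusted p = 0.00012). Tnn, the matrix protein tenascin-N, fell from 861 ± 413 to 2.57 ± 1.04 (−8.12 ± 0.49, adjusted p = 4.2e-05). Postn, the periostin of periosteum and ligaments, fell from 479 ± 210 to 7.44 ± 1.26 (−5.85 ± 0.43, adjusted p = 0.00013). The other genes with the largest falls were Col16a1, Aspn, Crispld2 and Aebp1, with log2 changes from −6.47 to −5.88.

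Of 23 fibrillar matrix and crosslinking genes, 21 fell and none rose (22 fell when adjusted over the list alone), with a median log2 change of −3.03 (camera adjusted p = 1.4e-14, and adjusted p = 0.16 with an estimated correlation). This median lay at percentile 15.85 of 10000 random lists matched on WT level, whose median was −2.56. The list thus did not stand apart from genes of like level. Its members Col6a2 and Col6a3, chains of collagen VI, fell by 5.74 and 5.78 on the log2 scale. Of 14 tendon and ligament markers, 6 fell and 1 rose, among them Fmod (−4.85 ± 0.54) and Col12a1 (−4.40 ± 0.43), with a median of −1.30 (adjusted p = 0.0032, and adjusted p = 0.21 with an estimated correlation). In the same libraries the background was 17.4% ± 8.31 of the reads in MUT and 0.772% ± 0.137 in WT. After background subtraction, which also scales to total reads, the fibrillar matrix list had a median of −1.83 (adjusted p = 1.7e-12, and adjusted p = 0.081 with an estimated correlation). Total-read scaling with no subtraction gave −1.80 (adjusted p = 2.9e-24) and quantile scaling −1.76 (adjusted p = 5.5e-11). Relative to the median of all genes under the same scaling, the list was at −3.20 in the deposited scaling, −2.91 with total-read scaling, −1.72 with quantile scaling and −2.10 after background subtraction. The tendon and ligament median was −0.34 with total-read scaling (−1.45 relative to all genes) and −1.43 after background subtraction.

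Bone genes fell as well. Of 22 osteoblast markers, 12 fell and none rose (15 fell over the list alone), with a median of −1.79 (adjusted p = 2.3e-06, and adjusted p = 0.24 with an estimated correlation), which was −0.96 under quantile scaling, −0.56 under total-read scaling (−1.67 relative to all genes) and −0.65 after background subtraction. Among 10000 random lists matched on WT level this median lay at percentile 51.41. MUT replicate 2 stood apart: the median of this list's changes from the WT mean was −0.83 there and −2.05 and −2.65 in MUT replicates 1 and 3, and after background subtraction −0.19, −0.70 and −1.35, against −0.19 in WT replicate 1. Runx2, the transcription factor that osteoblasts need, fell from 78.1 ± 22.2 to 11.1 ± 1.60 (−2.74 ± 0.38), and Pth1r, the parathyroid hormone receptor, fell from 131 ± 16.6 to 8.13 ± 3.92 (−4.07 ± 0.44). Of 15 osteocyte markers, 7 fell and 1 rose: Dmp1, a matrix protein of osteocytes, fell by 3.64 on the log2 scale, while Reln, an extracellular glycoprotein, rose 5.66-fold (list adjusted p = 0.011, and adjusted p = 0.25 with an estimated correlation). Of 17 osteoclast markers, 5 fell and 1 rose (adjusted p = 0.0036, and adjusted p = 0.21 with an estimated correlation). The 17 chondrocyte markers (1 higher, 3 lower, adjusted p = 0.095) did not pass the list test. The calls of the osteocyte and osteoclast lists ended under quantile scaling, the stricter filter and background subtraction (adjusted p from 0.18 to 0.49).

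**Figure D2:**
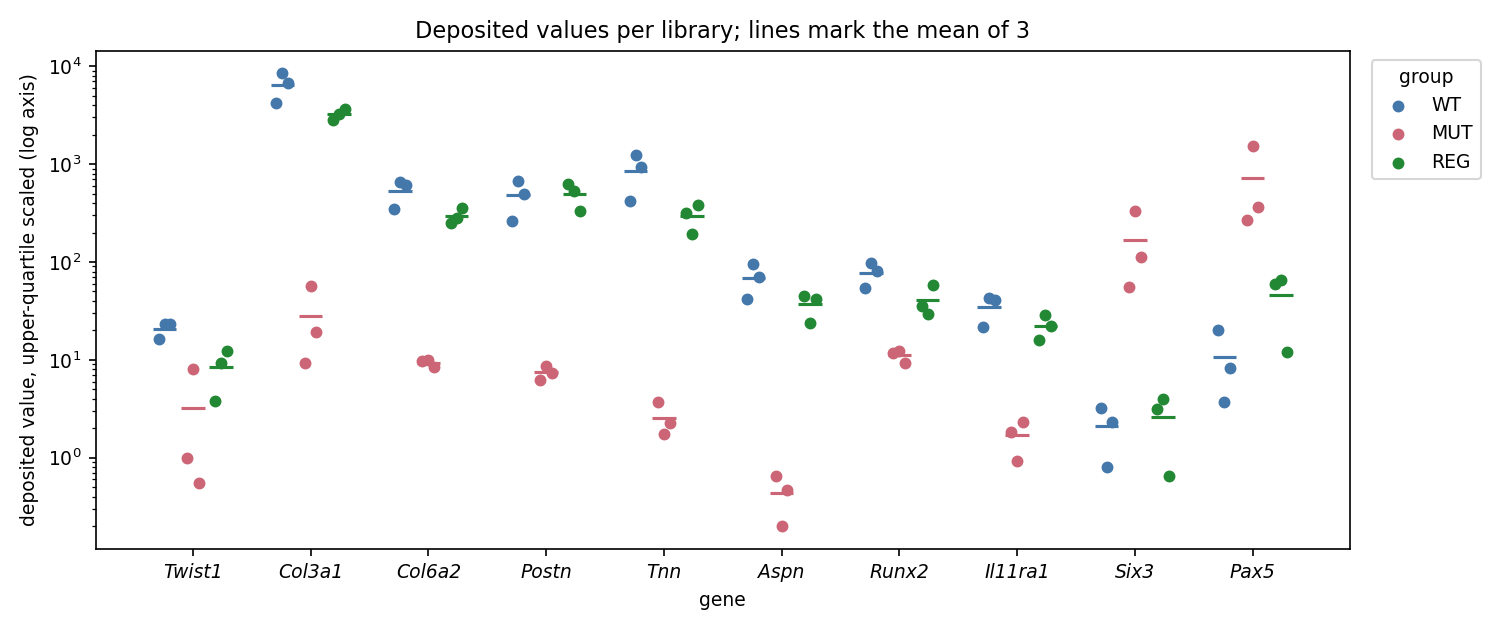
Deposited upper-quartile scaled values (log axis) of 10 genes in each library of WT, MUT and REG; points are libraries and lines the mean of 3. Col3a1 lies at 4212 to 8468 in WT, 9.35 to 56.4 in MUT and 2845 to 3686 in REG, while Six3 and Pax5 are highest in MUT.

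Suture and signalling lists moved the same way. Only the fibrillar matrix and osteoblast lists were set beside random lists matched on WT level. For all other lists, a fall shared by genes of like level cannot be told apart. Of 22 suture mesenchyme and stem cell markers, 13 fell and 1 rose (16 and 1 over the list alone), with a median of −1.55 (adjusted p = 0.00023, and adjusted p = 0.16 with an estimated correlation), which was −1.24 under quantile scaling, −0.43 under total-read scaling (−1.55 relative to all genes) and −0.73 after background subtraction. Prrx1, a transcription factor of craniofacial mesenchyme, fell by 2.68 ± 0.37 on the log2 scale. Of 24 genes of BMP and TGF-beta signalling, 14 fell and 1 rose, including Tgfb3 (−3.60 ± 0.44), with a median of −2.06 (adjusted p = 2.3e-06, and adjusted p = 0.16 with an estimated correlation). Of 23 genes known from craniosynostosis, a list that includes Twist1, 15 fell and 1 rose with a median of −1.80 (adjusted p = 5e-06, and adjusted p = 0.21 with an estimated correlation). Il11ra1, the interleukin 11 receptor, fell from 35.1 ± 11.8 to 1.69 ± 0.704, and Fgfr2, a receptor of fibroblast growth factors, fell from 92.1 ± 26.8 to 10.4 ± 0.122. FGF genes (8 lower, 2 higher of 18) and Hedgehog genes (6 lower, 1 higher of 12) had medians of −1.54 and −1.31 (adjusted p = 0.0063 and 0.0044, and adjusted p = 0.24 and 0.21 with an estimated correlation). With total-read scaling the BMP, craniosynostosis, FGF and Hedgehog medians were −0.88, −0.57, −0.44 and −0.15 (−2.00, −1.68, −1.55 and −1.26 relative to all genes), and after background subtraction −1.50, −1.03, −1.23 and −0.90. The suture, FGF and Hedgehog calls ended under the stricter filter (adjusted p = 0.19, 0.16 and 0.16). The 24 Wnt genes (4 lower, 2 higher) did not pass the list test (adjusted p = 0.20), although Sfrp2, a Wnt modulator, fell by 4.93 on the log2 scale.

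Markers of other cell types and tissues went both ways. The 13 mitochondrially encoded genes all fell, with a median of −3.32 (adjusted p = 2.7e-09, and adjusted p = 0.21 with an estimated correlation). Of 15 circadian clock genes 10 fell, with a median of −2.00 (adjusted p = 1.3e-05, and adjusted p = 0.21 with an estimated correlation). The mitochondrial and clock medians were −2.08 and −1.42 under quantile scaling, −2.09 and −0.95 under total-read scaling (−3.20 and −2.06 relative to all genes), and −1.84 and −1.52 after background subtraction. Keratinocyte markers (6 higher, 1 lower of 13, median 1.30, adjusted p = 0.012), neuron and astrocyte markers (6 higher, 1 lower of 14, median 1.55, adjusted p = 0.031) and B cell markers (3 higher of 15, median 1.06, adjusted p = 0.013) rose. With an estimated correlation these 3 lists had adjusted p = 0.16, 0.25 and 0.36, and under total-read scaling medians of 2.28, 2.54 and 2.13 (1.17, 1.43 and 1.02 relative to all genes). The B cell median was 2.16 after background subtraction. Erythroid markers (0.31, adjusted p = 0.65), cell cycle genes (0.14, adjusted p = 0.86) and neutrophil markers (−0.36, adjusted p = 0.42) were not called. After background subtraction all 3 were called higher (1.82, 1.22 and 1.05, adjusted p = 0.0070, 0.011 and 0.049), and under quantile scaling erythroid and cell cycle genes were (1.14 and 0.54, adjusted p = 0.0073 and 0.036). The B cell call also ended without MUT replicate 2 (median 1.20, adjusted p = 0.069) and with no filter (adjusted p = 0.0545), the keratinocyte call with MUT replicate 2 alone (adjusted p = 0.068), and the neuron call with no filter (adjusted p = 0.10), total-read scaling (adjusted p = 0.052) and MUT replicate 2 alone (adjusted p = 0.11). The largest increases were in Tafa1, Trp73os, Pax5, Six3, Trp63, Skint7 and Lonrf2, with log2 changes from 5.68 to 7.41, and Tafa1 and Trp73os were not called with MUT replicate 2 alone (adjusted p = 0.0594 and 0.0575). Six3, a transcription factor of the forebrain and eye, rose from 2.12 ± 1.23 to 168 ± 146 (5.84 ± 0.75, adjusted p = 0.0013), and Pax5, known from B cells and the midbrain, rose from 10.7 ± 8.39 to 727 ± 712 (5.89 ± 0.86, adjusted p = 0.0019). Among predicted genes, Gm10800 rose by 10.43 ± 0.64 on the log2 scale. It is among the 10 genes with the largest opposite changes in MUT vs WT and REG vs MUT, all predicted genes, of which 6 share over 50% of their 31-base sequences with other genes.

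In all, 10225 of 29107 genes were called in MUT vs WT, 5964 higher and 4261 lower, and groups did not overlap for 10192 of them. The 22 lists called, 3 higher and 19 lower, all lost the call with an estimated correlation (adjusted p from 0.16 to 0.40). The balance of directions depends on the scaling and on the filter. With total-read scaling, which moved the median of all genes from 0.18 to 1.11, 11734 genes were higher and 876 lower. Background subtraction gave 3245 and 824, and trimmed-mean scaling 4368 and 5135. The 10 times stricter filter, which tests 11449 genes, gave 910 higher and 3985 lower, with a median of all genes of −0.99. The count was 6584, 4511 and 5170 without WT replicates 1, 2 and 3, 6883, 9776 and 6894 without MUT replicates 1, 2 and 3, and 4065 with MUT replicate 2 alone.

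REG vs MUT asks what differs between the operated and the unoperated Twist1+/- suture. Matrix genes that had fallen in MUT were among the largest increases. Col3a1 rose from 28.4 ± 24.8 in MUT to 3252 ± 421 in REG (n = 3, log2 change 7.19 ± 0.58, adjusted p = 0.00031), Tnn from 2.57 ± 1.04 to 299 ± 99.0 (6.67 ± 0.49) and Postn from 7.44 ± 1.26 to 498 ± 153 (5.96 ± 0.43, adjusted p = 0.00017). Aspn, Timp1, Col6a3 and Col6a2 rose by 4.91 to 5.52 on the log2 scale. Timp1, an inhibitor of matrix metalloproteinases, was at 104 and 166 in REG replicates 1 and 2 and at 10.7 in REG replicate 3, and was not called with MUT replicate 2 alone (adjusted p = 0.079).

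Of the 23 fibrillar matrix genes, 20 rose and none fell (21 rose over the list alone), with a median of 2.92 (adjusted p = 3.6e-15, and adjusted p = 0.13 with an estimated correlation). Of 14 tendon and ligament markers, 4 rose and 1 fell, including Thbs4 (4.55 ± 0.50) and Col12a1 (4.42 ± 0.43; list adjusted p = 0.0049, and adjusted p = 0.25 with an estimated correlation). Of 22 osteoblast markers, 12 rose and none fell, with a median of 1.64 (adjusted p = 1.4e-07, and adjusted p = 0.31 with an estimated correlation). Alpl, the alkaline phosphatase of mineralizing cells, rose from 7.05 ± 4.36 to 65.3 ± 11.3, and Pth1r from 8.13 ± 3.92 to 61.6 ± 19.8. Of 17 osteoclast markers, 10 rose and 1 fell, with a median of 1.61 (adjusted p = 2.3e-05, and adjusted p = 0.13 with an estimated correlation). Mmp9, a protease of osteoclasts, rose from 41.6 ± 9.49 to 342 ± 80.5. The 15 osteocyte markers (4 higher, 2 lower) passed at adjusted p = 0.031 (adjusted p = 0.36 with an estimated correlation), and the call ended without REG replicate 3 (median 0.65, adjusted p = 0.12), with the pseudocount times 10 (adjusted p = 0.055) and with MUT replicate 2 alone (adjusted p = 0.080).

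Of 22 suture mesenchyme markers, 7 rose and 2 fell, with a median of 1.10 (adjusted p = 0.0023, and adjusted p = 0.25 with an estimated correlation). Prrx1 rose to 47.0 ± 8.20, a call that ended under quantile scaling, background subtraction and MUT replicate 2 alone (adjusted p = 0.064, 0.059 and 0.054), while Zic1, another transcription factor of the list, fell from 135 ± 80.8 in MUT to 10.3 ± 4.85 in REG, against 16.0 ± 2.48 in WT. Of 24 BMP and TGF-beta genes, 10 rose and 1 fell (median 1.52, adjusted p = 2.3e-05, and adjusted p = 0.13 with an estimated correlation), and of 23 craniosynostosis genes 9 rose and 3 fell (median 0.96, adjusted p = 0.0023, and adjusted p = 0.36 with an estimated correlation). Il11ra1 rose from 1.69 ± 0.704 to 22.4 ± 6.45. FGF genes (7 higher, 2 lower of 18) passed at adjusted p = 0.041 (adjusted p = 0.36 with an estimated correlation), and this call ended without MUT replicate 2 (median 0.79, adjusted p = 0.081) and without REG replicate 3 (median 0.50, adjusted p = 0.079), with the pseudocount times 10 (adjusted p = 0.052), array quality weights (adjusted p = 0.077), a replicate block (adjusted p = 0.060) and MUT replicate 2 alone (adjusted p = 0.052). The Hedgehog, chondrocyte and Wnt lists did not pass (adjusted p = 0.10, 0.26 and 0.41).

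Of 16 skeletal muscle markers, 9 rose (median 2.49, adjusted p = 2.3e-05, and adjusted p = 0.36 with an estimated correlation), and with REG replicate 3 alone the list had a median of 0.56 (adjusted p = 0.37), and its call also ended under the stricter filter (adjusted p = 0.21). Mitochondrially encoded genes rose (12 of 13, median 2.23, adjusted p = 6.6e-08), as did ribosomal protein genes (12 of 21, median 2.27, adjusted p = 4.6e-07), with adjusted p = 0.31 and 0.36 with an estimated correlation. Their medians were 1.34 and 1.40 under total-read scaling (2.38 and 2.44 relative to all genes) and 1.11 and 1.22 after background subtraction. Keratinocyte markers fell (6 of 13, median −1.40, adjusted p = 0.0078, and adjusted p = 0.13 with an estimated correlation). The keratinocyte median was −0.70 under quantile and −2.21 under total-read scaling. With MUT replicate 2 alone the ribosomal and keratinocyte calls ended (medians 0.26 and −1.20, adjusted p = 0.062 for both). Trp63, Lonrf2, C1ql4, Tafa1, Six3, Traf3ip3 and Hes7 had the largest falls, from −6.27 to −5.44 on the log2 scale, and the predicted gene Gm10800 fell by 11.01. The Tafa1 fall lost its call without MUT replicate 2 (−5.06, adjusted p = 0.051) and with MUT replicate 2 alone (−7.17, adjusted p = 0.0975).

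In REG vs MUT 10653 genes were called, 3432 higher and 7221 lower, and of 21 lists 20 rose and 1 fell, none of them called with an estimated correlation (adjusted p from 0.13 to 0.36). With trimmed-mean scaling 5985 genes were higher and 4962 lower, with quantile scaling 1890 and 2310, and with background subtraction 791 and 2976. Total-read scaling, which moved the median of all genes from −0.36 to −1.04, gave 982 and 11455. The 10 times stricter filter, which tests 11449 genes, turned the balance to 2780 higher and 872 lower. Under total-read scaling the medians of the suture, craniosynostosis, FGF, osteoblast and BMP lists in REG vs MUT were 0.24, 0.14, 0.21, 0.91 and 0.69 (1.28, 1.18, 1.25, 1.95 and 1.73 relative to all genes). Those of the fibrillar, tendon, osteoclast and osteocyte lists were 2.05, 0.15, 0.84 and 0.18 (3.09, 1.19, 1.88 and 1.22 relative to all genes). The suture, osteocyte, FGF and craniosynostosis calls ended after background subtraction (adjusted p from 0.091 to 0.60), under quantile scaling (adjusted p from 0.11 to 0.53) and under the stricter filter (adjusted p from 0.41 to 0.75).

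REG vs WT asks how far the operated Twist1+/- suture differs from the wild-type suture. No gene was called (0 of 29107, limma), while 2755 had an unadjusted p under 0.05, and the authors' table also holds 0 genes at an FDR under 0.05 for this pair. The genes of smallest p had, as values only, log2 differences of −4.11 ± 0.64 (Casc1), −3.91 ± 0.62 (Kcnj10), −3.30 (Vmn2r79), −2.38 (Dnajc5b) and −2.14 ± 0.38 (Klf2), with adjusted p from 0.35 upward. Higher in REG by value were Myh1, a myosin of fast muscle fibres (0.984 ± 0.131 in WT, 117, 105 and 6.16 in REG), Birc5, a gene of dividing cells (3.42 ± 1.46 against 15.5 ± 5.52), Hist1h2an, Slc13a5 and Tacc3, with adjusted p up to 0.48. Col3a1 had 3252 ± 421 in REG and 6468 ± 2140 in WT, Postn 498 ± 153 and 479 ± 210, and Runx2 40.8 ± 14.9 and 78.1 ± 22.2, without a call.

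Of the 34 lists, 16 passed in REG vs WT, 9 higher and 7 lower, though none with an estimated correlation (adjusted p from 0.26 to 0.51). Among the bone, matrix and signalling lists, osteoclast markers were higher (median 0.42, adjusted p = 0.00034, and adjusted p = 0.26 with an estimated correlation). Lower were craniosynostosis genes (median −0.77, adjusted p = 5.9e-05, and adjusted p = 0.32 with an estimated correlation) and Hedgehog genes (−0.73, adjusted p = 0.004, and adjusted p = 0.29 with an estimated correlation). The osteoclast, craniosynostosis and Hedgehog medians were 0.78, −0.41 and −0.37 under trimmed-mean scaling, 0.73, −0.43 and −0.40 under total-read scaling, 0.75, −0.45 and −0.40 after background subtraction, and 0.40, −0.37 and −0.44 with REG replicate 3 alone. Without REG replicate 1 the craniosynostosis median was −0.44. No member of these 3 lists was called over all genes, and 1 craniosynostosis gene was lower when adjusted over the list alone. Suture mesenchyme markers and BMP and TGF-beta genes passed at adjusted p = 0.041 and 0.045 (adjusted p = 0.38 for both with an estimated correlation). Both calls ended when WT replicate 2 was left out (medians −0.45 and −0.58, adjusted p = 0.14 and 0.20), WT replicate 3 (−0.52 and −0.68, adjusted p = 0.12 and 0.074), REG replicate 2 (−0.39 and −0.49, adjusted p = 0.085 and 0.069) or REG replicate 3 (−0.74 and −0.83, adjusted p = 0.13 for both). The BMP call also ended without REG replicate 1 (−0.62, adjusted p = 0.056) or MUT replicate 3 (−0.64, adjusted p = 0.057). Both also ended under trimmed-mean scaling (−0.19 and −0.30, adjusted p = 0.17 for both), total-read scaling (adjusted p = 0.084 and 0.10), background subtraction (adjusted p = 0.094 and 0.115), the stricter filter (adjusted p = 0.18 and 0.30), the pseudocount divided by 10 (adjusted p = 0.20 and 0.23) and REG replicate 3 alone (adjusted p = 0.058 and 0.095). Without REG replicate 3, 1596 genes were called (410 higher and 1186 lower), and with REG replicate 3 alone 0 were called and 743 had an unadjusted p under 0.05. On simulated data with 200 changed genes of 29107, the test found 2.5% of genes changed 4-fold, up or down, and 56.5% of those changed 8-fold. These shares hold for that setting and do not give the share found where many more genes differ.

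**Figure D3:**
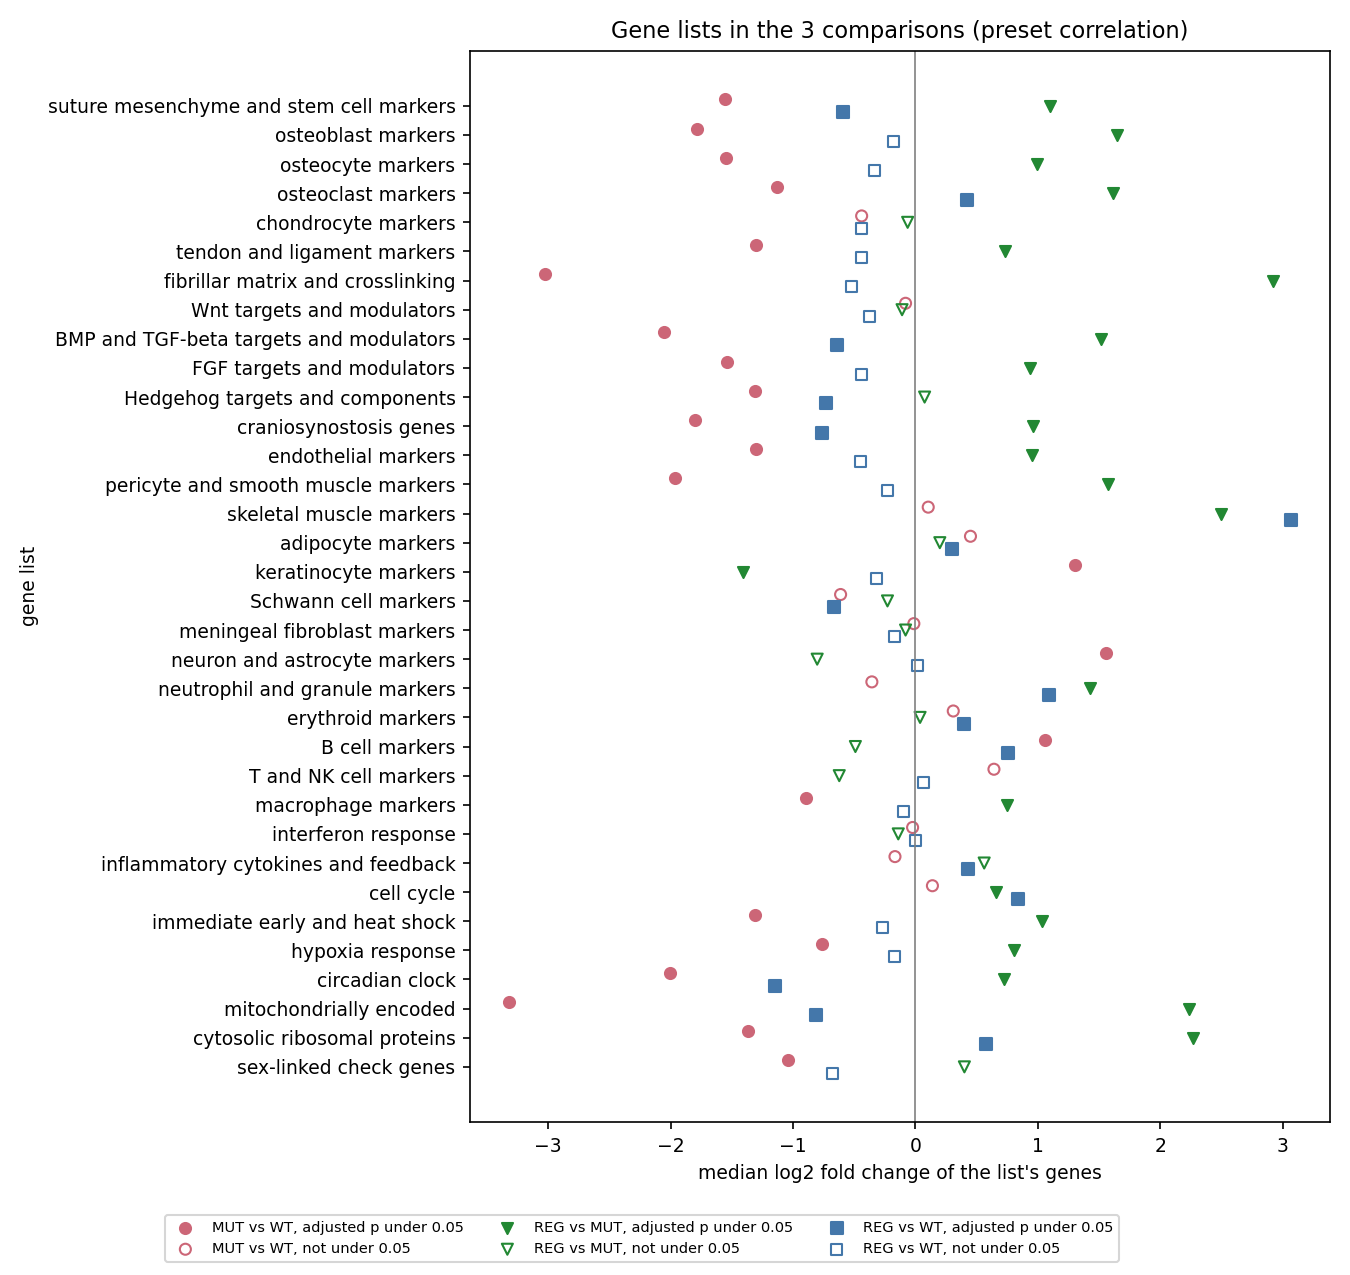
Median log2 change of the measured members of each list in MUT vs WT (circles), REG vs MUT (triangles) and REG vs WT (squares); filled symbols had an adjusted p under 0.05 at the preset correlation, and no list did at the estimated correlation. Fibrillar matrix genes lie at −3.03 in MUT vs WT and 2.92 in REG vs MUT. Among the filled symbols, under total-read scaling the medians of macrophage, hypoxia and sex-linked genes in MUT vs WT, and of cell cycle, hypoxia and clock genes in REG vs MUT, change sign; medians of some open symbols change sign too.

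Of the 10225 genes called in MUT vs WT, 7924 were called in the opposite direction in REG vs MUT and 1 in the same direction. In REG vs WT 0 of them were past the threshold, but so were 0 of all 29107 genes, so that count is not particular to them. Of the 4261 genes lower in MUT, 2623 (61.6%) rose in REG, among them Col3a1, Tnn, Postn and Pth1r. Of the 5964 genes higher in MUT, 5301 (88.9%) fell in REG, among them Six3 and Trp63. After background subtraction 824 genes were lower in MUT, of which 408 rose in REG. The genes lower in MUT had a median REG minus WT difference of −0.47, with −0.63, −0.72 and −0.01 in REG replicates 1 to 3. The median difference was −0.18 over all genes and −0.08 for the genes higher in MUT. Log2 changes of both comparisons had a Pearson correlation across genes of −0.86, where genes are not independent replicates and the shared MUT libraries alone gave −0.50 in simulations. In the cross-fit that shares no library it was −0.70, and −0.57 after background subtraction. The 3 MUT libraries share a raised background and a low mitochondrial share, which the cross-fit does not remove. A quality difference common to them would also give a negative correlation and cannot be told apart here from an effect of surgery. The opposite count was 3993 without WT replicate 2, 4411 without WT replicate 3, 5260 without MUT replicate 3 and 2942 after background subtraction. In these settings MUT vs WT itself had 4511, 5170, 6894 and 4069 calls. Without REG replicate 3, where MUT vs WT had 11306 calls, 837 of the genes were still past the threshold in REG vs WT.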

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

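Total-read scaling, background subtraction and MUT replicate 2 alone were chosen after seeing the data; the other alternatives before. Counts of called genes in MUT vs WT (10225) were 5181 with quantile scaling, 4895 with the 10 times stricter filter (which tests fewer genes), 17589 with array quality weights, 4069 with background subtraction and 4065 with MUT replicate 2 alone, and 4511 to 12756 when 1 library was left out. REG vs MUT (10653) gave 4200 with quantile scaling, 3652 with the stricter filter, 5689 with only the 2 groups compared, 3767 with background subtraction and 4264 with MUT replicate 2 alone, and 7540 to 11706 with 1 library left out. REG vs WT (0) gave 1596 with REG replicates 1 and 2 alone, and 0 to 1596 with 1 library left out. The opposite count (7924) was 3179 with quantile scaling, 3025 with the stricter filter, 2942 with background subtraction, 3244 with MUT replicate 2 alone, and 3993 to 9711 with 1 library left out. The number still past the threshold in REG vs WT (0) was 837 with REG replicates 1 and 2 alone, and 0 to 837 with 1 library left out. The correlation of −0.86 became −0.70 in the cross-fit. The cause of these shifts was not tested, apart from the fewer genes of the stricter filter, the fewer libraries of the left-out and lone settings, and the shared libraries that the cross-fit removes. Background subtraction tested 23863 genes and total-read scaling 30353, against 29107 in the main fit, so their counts also rest on another set of genes. A lone library is assumed to vary like the other groups.

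Twist1 in MUT vs WT (−3.26) was −2.90 with background subtraction and −1.31 with MUT replicate 2 alone. In REG vs MUT (1.85) it was called with trimmed-mean scaling (2.41), array quality weights (2.23) and without MUT replicate 2 (range 1.23 to 2.83 with 1 library left out), and turned to −0.0946 with MUT replicate 2 alone. Uty in MUT vs WT turned to 0.0637 with total-read scaling. Called lists numbered 22, 21 and 16 in the 3 comparisons and 0, 0 and 0 with an estimated correlation. REG vs MUT gave 12 with the stricter filter and 13 with background subtraction, and REG vs WT gave 0 with fry's directional test and 2 with its mixed test. Of 162 called values of named genes, 131 stayed called with quantile scaling and 161 with trimmed-mean scaling, and 111 of 157 with background subtraction. The causes were not tested.

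With the replicate numbers as a replicate block, 8766, 9373 and 0 genes were called in MUT vs WT, REG vs MUT and REG vs WT, Twist1 kept −3.26 (adjusted p = 0.013), 22, 20 and 17 lists were called, and 6603 genes moved back. A library's closest partner carried its own number in 1 of 9 cases, which gives no sign of pairing but cannot exclude it. The numbers are those of the sample titles, and those in the library names were not tried. The alternative from the other deposited table was not run, since it holds no values per sample, and tests for whole read counts do not apply to these values.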

Other observations

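The tests of depth, of dilution as the only cause, of both forms of a fall shared with osteoblast markers and of the sequencing run were chosen only after the result was seen, as were total-read scaling, background subtraction and MUT replicate 2 alone. Skeletal muscle markers had a median of 3.07 in REG vs WT (0 of 16 called, 13 higher over the list alone, camera adjusted p = 6e-19, and adjusted p = 0.26 with an estimated correlation), with a median of 0.68 in REG replicate 3 alone. Acta1, the actin of skeletal muscle, had 130, 111 and 13.1 RPM in the REG replicates and from 2.25 to 10.3 in WT. Neutrophil markers (median 1.09, 5 of 16 higher over the list alone, adjusted p = 3.5e-11, and adjusted p = 0.27 with an estimated correlation) and cell cycle genes (median 0.84, 6 of 20 higher over the list alone, adjusted p = 1.6e-11, and adjusted p = 0.26 with an estimated correlation) were higher too, at 1.32 and 1.40 in REG replicate 3 alone. B cell markers (median 0.76, adjusted p = 9e-06), erythroid markers (0.40, adjusted p = 0.00022), ribosomal protein genes (0.58, adjusted p = 0.00034), adipocyte markers (0.30, adjusted p = 0.017) and inflammatory cytokines (0.43, adjusted p = 0.041) were also higher, with adjusted p from 0.26 to 0.50 with an estimated correlation. Under trimmed-mean scaling the medians of B cell, erythroid, ribosomal, adipocyte and cytokine genes were 1.03, 0.78, 0.98, 0.62 and 0.70. Erythroid markers lost the call without REG replicate 3 (median 0.07, adjusted p = 0.15). Adipocyte markers lost it without REG replicate 1 or 2 (0.17 and 0.20, adjusted p = 0.056 and 0.051), and cytokines without WT replicate 1 or 2 or REG replicate 1 or 2 (0.03, 0.42, 0.47 and −0.03, adjusted p = 0.22, 0.052, 0.13 and 0.62). The cytokine call also ended under trimmed-mean, quantile and total-read scaling (adjusted p = 0.087, 0.059 and 0.074), background subtraction (adjusted p = 0.0665), the stricter filter (adjusted p = 0.18) and array quality weights (0.14, adjusted p = 0.25). With REG replicate 3 alone cytokines, adipocyte markers and ribosomal protein genes were at −0.54, −0.15 and 0.21, without a call (adjusted p = 0.095, 0.34 and 0.14).

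Circadian clock genes were lower in REG than WT (median −1.14, 0 of 15 called, adjusted p = 7.7e-05, and adjusted p = 0.32 with an estimated correlation), at −0.21 in REG replicate 3 alone, where the list was not called (adjusted p = 0.16). Mitochondrially encoded genes (−0.81, adjusted p = 0.0059, and adjusted p = 0.51 with an estimated correlation) and Schwann cell markers (−0.67, adjusted p = 0.013, and adjusted p = 0.29 with an estimated correlation) were lower as well. Their medians were −0.41 and −0.37 under trimmed-mean scaling and −0.46 and −0.37 under total-read scaling, and the mitochondrial share of reads was 12.5% in REG and 11.4% in WT. The mitochondrial call ended without WT replicate 2 (−0.61, adjusted p = 0.069) or REG replicate 1 (−0.43, adjusted p = 0.13), with the pseudocount divided by 10 (adjusted p = 0.057) and REG replicate 3 alone (adjusted p = 0.054), and the Schwann call without REG replicate 2 (−0.78, adjusted p = 0.051) or REG replicate 3 (−0.92, adjusted p = 0.13), under the stricter filter (adjusted p = 0.082) and with array quality weights (adjusted p = 0.068). The lists that passed in MUT vs WT and are not described above were endothelial, pericyte, macrophage, immediate early, hypoxia, ribosomal and sex-linked genes, all lower, with adjusted p from 0.00034 to 0.043 and, with an estimated correlation, adjusted p from 0.16 to 0.40. All of these except the pericyte list lost the call under the stricter filter (adjusted p from 0.16 to 0.51). The endothelial, hypoxia, ribosomal and sex-linked calls ended under quantile scaling (adjusted p from 0.080 to 0.18), and the endothelial, macrophage, hypoxia and ribosomal calls after background subtraction (adjusted p from 0.083 to 0.44). Endothelial, pericyte and immediate early medians were −1.30, −1.96 and −1.31, and −0.22, −0.79 and −0.27 under total-read scaling (−1.33, −1.90 and −1.38 relative to all genes). Ribosomal protein genes had a median of −1.37, −0.16 under total-read scaling (−1.27 relative to all genes) and 0.60 with MUT replicate 2 alone. Under total-read scaling the medians of macrophage, hypoxia and sex-linked genes were 0.04, 0.11 and 0.14, the last 2 without a call (adjusted p = 0.054 and 0.10). The sex-linked call (−1.04) ended without WT replicate 1 or 3, MUT replicate 1 or 2, or REG replicate 3 (medians −1.11, −1.01, −1.004, −1.03 and −1.04, adjusted p = 0.0508, 0.051, 0.0822, 0.0665 and 0.0548), with the pseudocount divided by 10 (adjusted p = 0.051) and with only 2 groups compared (adjusted p = 0.058). Among their members, Pdgfrb, a receptor of pericytes, fell by 3.50 and Jun, an immediate early transcription factor, by 4.21 on the log2 scale. In REG vs MUT the lists not described above were neutrophil (median 1.42, adjusted p = 4.6e-05), pericyte (1.57, adjusted p = 0.00067), immediate early (1.03, adjusted p = 0.00043), cell cycle (0.66, adjusted p = 0.0017), macrophage (0.75, adjusted p = 0.0022), endothelial (0.96, adjusted p = 0.0038), clock (0.72, adjusted p = 0.0075) and hypoxia genes (0.80, adjusted p = 0.024), all higher, with adjusted p from 0.13 to 0.36 with an estimated correlation. Cell cycle, hypoxia and clock medians were −0.18, −0.07 and −0.09 under total-read scaling (0.86, 0.97 and 0.95 relative to all genes). All 8 except the pericyte list lost the call under the stricter filter (adjusted p from 0.088 to 0.64). The neutrophil, cell cycle, endothelial, clock and hypoxia calls ended under quantile scaling (adjusted p from 0.052 to 0.42) and after background subtraction (adjusted p from 0.091 to 0.43). The clock call also ended without REG replicate 3 (0.41, adjusted p = 0.075), the clock and cell cycle calls with MUT replicate 2 alone (adjusted p = 0.066 and 0.077), and the hypoxia call with REG replicate 3 alone (adjusted p = 0.052). Casc1, Kcnj10 and Klf2, which were chosen for REG vs WT, had means of 228, 61.7 and 76.9 in WT, 19.2, 6.10 and 15.5 in MUT, and 15.9, 4.90 and 16.7 in REG. Hbb-bs, a globin gene chosen after its values were seen, had 132 to 502 RPM in WT, 940 to 1509 in MUT and 819 to 2455 in REG. Reads on Xist (24.4 to 379 RPM) and on the Y-linked Ddx3y (0.692 to 34.3 RPM) were found in all 9 libraries. Their balance differed between libraries: MUT replicate 2 had 338 RPM on Xist and 0.692 on Ddx3y, and REG replicate 1 had 24.4 and 26.9. Sex was not part of the fit. The sex-linked list holds Xist beside Y-linked genes, so its median does not give a direction of sex.

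The first pattern is the 5964 genes higher in MUT than WT, which include Six3, Pax5 and many genes near 0 in WT. Fewer reads in MUT argue poorly for it, since MUT replicates 1 and 3 had reads on more genes than any WT or REG library, by at least 10.6 percentage points, though MUT replicate 2, with the fewest reads, had reads on fewer (80.2%, against 81.8% to 85.6%), and GC content is not the whole cause, since 66.4% of the genes with a GC value (3891 of 5860) were still higher once each library's GC trend was removed. For the 663 genes with a WT mean of 1 or more, the median density in MUT was 5.96 times that of receptor genes. These genes were chosen for being higher in MUT than WT, which favours a density above that of receptor genes. The ratio was above the bound of 2 set in advance, but for this reason it cannot exclude even background reads as a cause. For the 5301 genes with a WT mean under 1 this ratio was 1.85, between the bounds of 1.5 and 2 set in advance. Even background may account for part of them and cannot be told apart from other sources. The ratio was 0.63 for 1183 protein-coding genes, other than receptors, at or under the receptor median in WT. Their library medians were 0.92, 0.55 and 0.88 in MUT replicates 1 to 3, so the pooled ratio rests much on MUT replicate 2, with the fewest reads. These genes were also chosen for a low density in WT. The ratio therefore does not show whether receptor density overstates the background on such genes. Uneven background, RNA of other tissues and an effect of genotype or of suture fusion, which was not measured here, stay open as untested.

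The second pattern is the lower fibrillar matrix genes in MUT, to which dilution by background may contribute. The list's median of −3.03 lay at percentile 15.85 of 10000 random lists matched on WT level (random median −2.56, lowest −3.80). It thus did not stand out from genes of like level, but the draw cannot tell dilution from other causes of such a fall. Total-read scaling alone moved the median to −1.80, and subtraction then left it at −1.83. Relative to all genes these medians were −2.91 and −2.10. As the only cause, even background is excluded, since after its subtraction the list's median was −1.83, with −1.79 to −1.40 in the MUT libraries and −0.42 to 0.27 in WT (adjusted p = 1.7e-12, and adjusted p = 0.081 with an estimated correlation), and −1.80 under total-read scaling without subtraction. The main fit argues against a fall of equal size in osteoblast markers but does not exclude it. The gap between the medians of both lists changed by −2.57 from WT to MUT. The difference of their median changes was −1.24, with −1.34 to −0.92 in the MUT libraries and −0.23 to 0.20 in WT. After background subtraction it was −1.18, with −1.21 to −0.43 in MUT, −0.23 to 0.19 in WT and −0.50 to 0.13 in REG. MUT replicate 3 lies within REG there, and the bound for this test was chosen after the result was seen. A shared fall that grows with the WT level may contribute, since pairs of random lists matched on level differed by −0.77 and the real difference lay at percentile 17.83 of them. A change in tissue composition, RNA quality in the MUT libraries and the genotype stay open as untested.

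The third pattern is that REG replicates 1 and 2 lay further from WT than REG replicate 3. Gene length is excluded as the whole cause, since the genes called came to 63.0% of their number (994 against 1578) once each library's length trend was removed, and 876 of the 1578 were still called. The 1596 genes called for REG replicates 1 and 2 against WT cannot be told apart from an effect of their sequencing run, since no WT or MUT library is known to share it. A response to surgery that differs between samples stays open as untested.

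The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. The real count was 10225 and the highest of the other splits 0 in MUT vs WT, 10653 and 73 in REG vs MUT, and 0 and 0 in REG vs WT, where all 10 splits gave as many. In the first 2 comparisons 1 split, the real one, gave a count as large.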
